A study of Mus musculus with 6 samples.

How the data were processed

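Total RNA from 6 mouse prostate tumours, 3 PtenL/W;K-ras and 3 Pten null, was hybridised to Affymetrix arrays, per the labels' protocols and the series description, which says that RNA came from prostate lobes dissected from individual animals. The deposited values are log2 expression per probe set that the authors made with RMA, per the submitters' processing notes. RMA corrects the background, quantile-normalizes the arrays and summarises the probes of a probe set. Its version and settings are not given in the sources used here, and neither is a genome build, so no coordinates are printed. RMA compresses differences near the low and the high end of the scale, and its quantile step gives all arrays nearly one distribution, so values can be compared between arrays for one probe set but not between probe sets. The deposited columns carry each array's own sample name, which fixed its group and replicate number from the labels. No column was left unused. No 2 arrays held identical values.

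The deposited table has 45101 probe sets, 64 of them controls. The platform annotation gives 1 gene for 34958 probe sets (13 of these are controls), several for 932 and none for 9211. Probe sets with several genes or none were left out of the gene-level tests. Gene IDs of 34754 of the single-gene probe sets were found in a RefSeq gene table of assembly GRCm38.p6, used for names only, and no symbol changed. Some list genes have no single-gene probe set in this annotation and were not analysed here, Pten and Kras among them, so the planned result for the 2 altered genes has no value. For each of 18194 genes the probe set with the highest mean over the 6 arrays was used, which for 2 genes was a control probe set, and 9012 genes had several probe sets. Of the 30 genes named for the size of their difference, 18 had several, and for none of the 18 did a probe set point the other way. For 9 of the 18 every probe set differed by at least 1 (log2). In the rest at least 1 probe set changed less, and some hardly changed, such as 1 each for Trp63 (−0.012), Tenm2 (−0.003), St6galnac2 (−0.12) and Adamts12 (0.19).

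Genes were tested with limma 3.58.1 (lmFit and eBayes, no trend, not robust) in R 4.3.3, PtenL/W;K-ras minus Pten null, with group as the only term, and p-values were adjusted by the method of Benjamini and Hochberg over all genes. A gene was called at an adjusted p under 0.05, and counted again with a log2 difference of at least 1. SE values are limma's moderated standard errors. A list of genes was tested with camera (preset correlation 0.01, at least 5 measured members, adjusted over 30 lists), with the correlation estimated per list and with fry as alternatives. Camera compares a list with all other genes, while fry asks whether the genes of a list move on their own. Of 31 lists written from general knowledge before the data were examined, 30 had enough measured members, and the erythroid list did not. A count adjusted over the list alone uses the list's own p-values. The directional fry test called 1 list, and fry's test for change in either direction (mixed) called 13. With 3 arrays against 3, an exact permutation test of a single value cannot go below p = 0.1.

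The test, the lists, the alternatives and the rule for named genes were set before the data were examined. The rule takes Pten and Kras, the 15 higher and 15 lower called genes with the largest absolute log2 difference and no overlap between groups, and up to 4 members of each list with the largest absolute moderated statistic. Alternatives were the mean of a gene's probe sets, a filter at the median level, subtraction of array medians, a second quantile normalization, eBayes with trend and robust, array weights, the replicate number as a block, each array left out, all probe sets, an ordinary two-sample test with equal variances, treat against a log2 difference of 0.5, and camera on ranks. Leaving out array 2 of both groups was added after seeing the data.

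The code was tested on simulated data before use, with 18194 genes drawn from the real means and residual variances for PtenL/W;K-ras minus Pten null and 200 genes changed. It recovered 32% of 50 genes changed by 1 on the log2 scale, 76% of 50 changed by 2, 98% of 50 changed by 3 and 92% of 50 changed by 4, with 6 false calls. Of 30 simulated lists of 15 genes, the 5 that were shifted by 1 were called and none of the others was. The simulated genes were drawn independently, while the estimated correlation reached 0.923 in a real list (proliferation). The simulation therefore does not show how often camera calls a list falsely in these data. RNA quality was read from the 3' minus 5' difference of the beta-actin and Gapdh control probe sets, which lay between 0.71 and 1.07 and between −0.22 and 0.045 on the 6 arrays. The precision is limited by the number of arrays.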

Results

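Gene expression was measured in mouse prostate tumours of 2 genotypes on Affymetrix arrays, with 3 arrays per genotype and 1 array per animal. The first group is labelled Pb-Cre+;PtenL/W;K-rasG12D/W, called PtenL/W;K-ras here, and carried a prostate-specific Cre recombinase (probasin promoter), a Pten genotype labelled L/W and an activated K-ras allele. The second group is labelled Pten null. Every tumour came from an animal older than 20 weeks. The study asked whether activating the RAS/MAPK pathway together with Pten loss goes with epithelial-mesenchymal transition (EMT), the change of epithelial cells towards a mesenchymal state. The labels give L/W for Pten in the K-ras group and the series description speaks of Pten loss, so the state of the second Pten allele in these tumours is left as labelled. As labelled, the groups differ at both Pten and K-ras, and no group differs at only 1 of them. No difference below can therefore be assigned to K-ras activation rather than to Pten. No probe set was named for Pten or Kras in the annotation used here, so neither gene could check the labels. The values are log2 expression, with medians between 6.34 and 6.41 on the 6 arrays. Over 18194 genes, Pten null arrays 1 and 3 correlated at r = 0.991, and the 2 K-ras arrays most alike, 1 and 3, at r = 0.974. Pten null array 2 and PtenL/W;K-ras array 2 correlated with the other arrays of their own group at 0.942 or less. The first principal component, with 40.5% of the variance, separated the genotypes, and the second, with 29.7%, set array 2 of both groups (−75.37 for Pten null, −31.58 for PtenL/W;K-ras) apart from the other 4 arrays (22.24 to 33.54). Only 3 arrays per group limit the precision of every value below.

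Genes called as higher in PtenL/W;K-ras tumours included the secreted protease genes Mmp13, Mmp10 and Adamts12. Mmp13, a collagenase, read 9.78 ± 0.42 against 3.80 ± 0.19 in Pten null tumours (log2, mean ± SD, n = 3 each). Mmp10, the protease stromelysin-2, was higher, at 8.41 ± 0.08 against 5.47 ± 0.16. Both had an adjusted p of 0.0039 in the limma fit. The secreted metalloprotease Adamts12 was higher by 3.62 ± 0.38 (log2, SE). Among matrix genes, the collagen genes Col8a1 and Col5a2 were higher by 2.99 ± 0.21 and 2.55 ± 0.29, and Ecm1, extracellular matrix protein 1, by 2.59 ± 0.31. Hs3st1, a heparan sulfate sulfotransferase, was higher by 2.72 ± 0.17 and Chsy3, a chondroitin sulfate synthase, by 3.30 ± 0.39. RMA compresses low values, so no single gene's difference is given as a fold, and 2-fold in the counts below stands for a log2 difference of 1. The sizes are least certain for Chsy3, Mmp13, Cd200r3, Sectm1a and Tenm2, whose low groups had means between 3.13 and 4.10. Igfbp3, which binds insulin-like growth factors, differed by 2.50 ± 0.15 and Pmepa1, a membrane protein induced by TGF-beta, by 2.43 ± 0.23. The remaining 5 of the 15 higher genes with the largest differences were Cd200r3 (3.24 ± 0.35), the cationic amino acid transporter gene Slc7a2 (3.03 ± 0.37), Oaf (2.80 ± 0.33), the RNA-binding protein gene Celf4 (2.53 ± 0.28) and Srpx2 (2.48 ± 0.21).

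Genes with lower expression in PtenL/W;K-ras tumours included the basal-cell transcription factor gene Trp63 and the receptor genes Bmpr1b and Fgfr3. Bmpr1b, a BMP receptor, read 5.69 ± 0.85 against 10.49 ± 0.65 (log2, mean ± SD, n = 3 each). Slco1a5, an organic anion transporter, differed by −4.66 ± 0.46 (log2, SE) and Sectm1a by −4.41 ± 0.21, with adjusted p of 0.0364 and 0.00465 in limma. Trp63 read 4.56 ± 0.46 against 8.73 ± 0.38. Cited1, a transcriptional co-regulator, differed by −4.01 ± 0.31, St6galnac2, a sialyltransferase, by −3.63 ± 0.43 and Cyp2e1, a cytochrome P450, by −3.38 ± 0.36. The glutathione transferase gene Gstm7 differed by −2.76 ± 0.28, the HLH protein gene Id4 by −2.73 ± 0.31, the proton pump subunit gene Atp6v1c2 by −2.72 ± 0.24 and Tenm2 by −2.72 ± 0.24. Eaf2 and Fam234b differed by −2.60 ± 0.29 and −2.56 ± 0.24. Lgals7, galectin-7, differed by −2.47 ± 0.11 with an adjusted p of 0.0039, and the receptor gene Fgfr3 by −2.40 ± 0.24.

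In all, 102 of 18194 genes passed an adjusted p of 0.05 in limma, 71 of them higher and 31 lower in PtenL/W;K-ras tumours. Of these, 68 higher and 27 lower genes differed by 2-fold or more. The groups did not overlap at 4436 genes, 24.4% of those tested, where chance gives 10%. Single arrays moved the number of called genes: it was 1 without PtenL/W;K-ras array 1, 303 without array 2 and 66 without array 3 of that group, and 3, 207 and 1 without Pten null arrays 1, 2 and 3. Without both arrays that stand apart (array 2 of each group), an alternative chosen after seeing the data, 1034 genes were called, 98 of the 102 among them. The ordinary two-sample test, which does not moderate variances across genes, called 1 gene and treat 13, while 176 probe sets were called over all probe sets, 213 genes after the filter at the median level and 1561 with array weights. With the replicate number as a block, limma called 0 genes (smallest adjusted p = 0.0623).

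**Figure D1:**
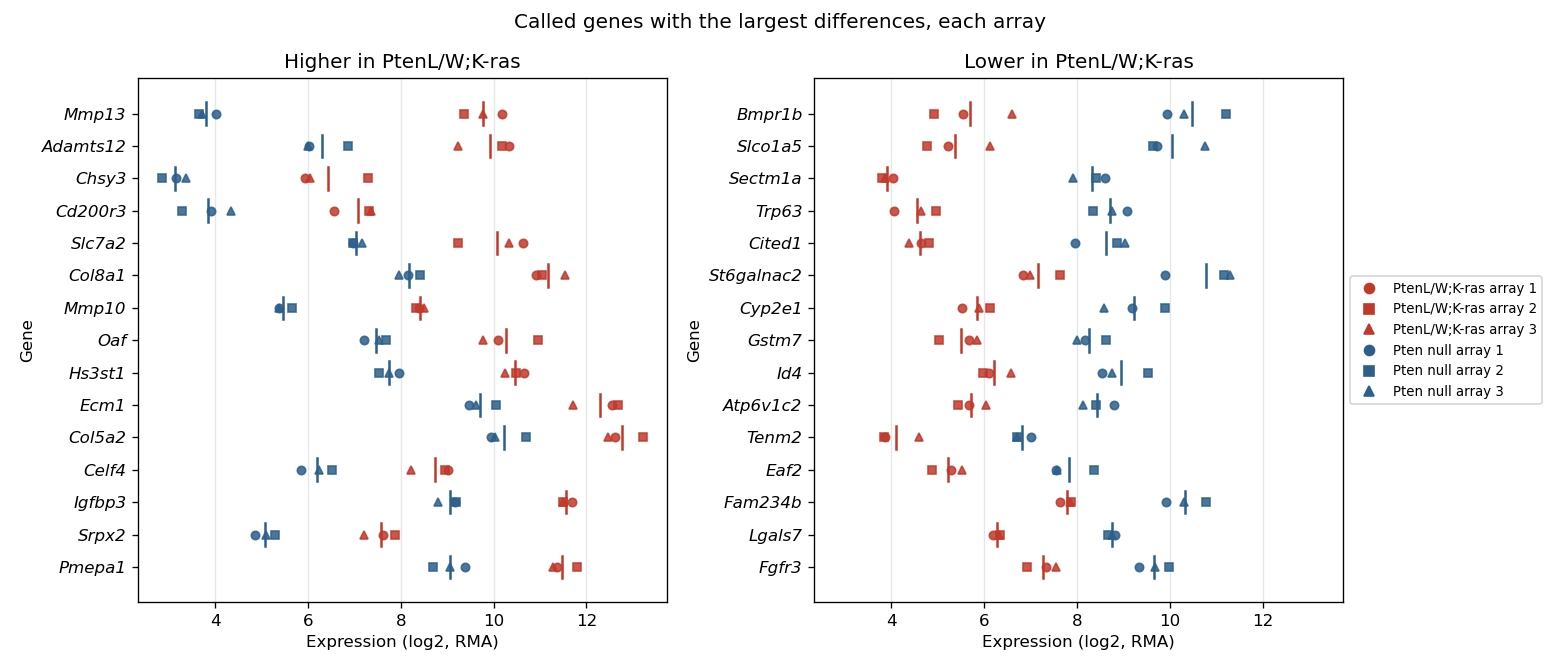
Expression (log2, RMA) of the 15 higher and 15 lower called genes with the largest differences, 1 marker per array and a vertical line at each group's mean. The rule that chose these genes asked for no overlap between the genotypes. At Mmp13 the PtenL/W;K-ras arrays lie between 9.36 and 10.19 and the Pten null arrays between 3.66 and 4.01.

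The list of EMT and mesenchymal genes had a median difference of 1.77 (log2), and 21 of its 23 measured members were higher in PtenL/W;K-ras tumours, 18 of them with no overlap between the groups. Called over all genes were Zeb2, a transcription factor that represses E-cadherin (1.99 ± 0.13, SE), the cytokine gene Tgfb1 (1.79 ± 0.14) and the transcription factor gene Foxc2 (1.77 ± 0.19). The matrix protein gene Tnc read 3.33 ± 0.45 higher with an adjusted p of 0.0522. Adjusted over the list alone, 18 members passed, all higher. The list was called by camera (adjusted p = 2.1e-16), not with an estimated correlation (adjusted p = 0.146). It was the 1 list called by the directional fry test (adjusted p = 0.00791), and camera called it in each fit without 1 array. Fry's test for change in either direction, which says nothing of direction, called this list (adjusted p = 0.000191) and 12 others: FOXO targets (0.000191), basal epithelium and nerve (0.00123 each), fibroblast (0.0021), RAS/MAPK output (0.00337), adipocyte (0.011), endothelium and B cell (0.0161 each), neutrophil and urothelium (0.0188 each), and stem and prostate secretory genes (0.0288 each).

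The list of RAS/MAPK output genes had a median difference of 0.95 (log2), with 23 of 24 members higher in PtenL/W;K-ras tumours and 13 without overlap. Emp1, an epithelial membrane protein, was called over all genes (2.16 ± 0.20, SE). Plaur, the urokinase receptor gene, read 2.01 ± 0.28 higher, the receptor gene Epha2 1.54 ± 0.25 and the EGF-family ligand gene Hbegf 1.84 ± 0.32, with adjusted p between 0.0535 and 0.0735. Adjusted over the list alone, 11 members passed, all higher. By camera the list was called (adjusted p = 2.3e-10), and with an estimated correlation it was not called (adjusted p = 0.38). The list was called in each fit without 1 array.

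Epithelial junction and identity genes had a median difference of −0.90 (log2), with 20 of 26 members lower in PtenL/W;K-ras tumours and 9 of them without overlap. No member passed over all genes or adjusted over the list alone. The tight-junction gene Cldn3 read −1.16 ± 0.32 (SE), the transcription factor genes Ovol2 and Grhl2 −0.79 ± 0.29 and −1.83 ± 0.70, and the membrane protease gene Prss8 −2.31 ± 0.88. Most of the difference lay in PtenL/W;K-ras array 2, whose median over the list was −2.67 against the Pten null mean, where arrays 1 and 3 were at −0.12 and −0.30. The list was called by camera (adjusted p = 0.00661) but not with an estimated correlation (adjusted p = 0.66) or without PtenL/W;K-ras array 2 (median −0.11, adjusted p = 0.0701). Without PtenL/W;K-ras array 1 the median was −1.40 (adjusted p = 1.13e-05) and without array 2 of both groups −0.47 (0.000312).

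Basal epithelial genes went both ways. Trp63 was called. Krt5, a basal keratin, read −3.10 ± 0.43 (SE) and Col17a1, a hemidesmosome collagen, −4.29 ± 0.76, while the integrin gene Itga6 read 1.40 ± 0.32 higher, each without overlap between the groups. Adjusted over the list alone, 6 of 12 members passed as lower and 3 as higher. The list as a whole was not called by camera (median −0.39, adjusted p = 0.139). Camera called it as lower without Pten null array 2 (median −0.58, adjusted p = 0.0236) and with the mean of probe sets (−0.68, 0.027), the median was −0.64 without array 2 of both groups (0.10), and after the filter the median turned to 0.56 (0.751). Of 10 luminal genes, Dpp4 and Cldn3 passed as lower and Krt7 as higher, adjusted over the list alone. Dpp4 read −2.90 ± 0.59, Krt7 1.86 ± 0.40 and Cldn10 −1.94 ± 0.90, and camera did not call the list (adjusted p = 0.555), with a median of 0.037 and a mean of −0.35. None of 16 squamous genes passed adjusted over the list alone, and the list was not called (adjusted p = 0.808). Of the 16, 10 had a positive and 6 a negative difference. The desmosomal cadherin gene Dsc3 read −3.08 ± 0.74, Krt1 −0.50 ± 0.18, Krtdap −1.05 ± 0.47 and the involucrin gene Ivl 1.33 ± 0.65.

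Prostate secretory and androgen-regulated genes were lower in PtenL/W;K-ras tumours, with a median difference of −1.93 (log2) and 12 of 15 members lower. The prostatic acid phosphatase gene Acpp read −2.40 ± 0.39 (SE), Azgp1 −3.03 ± 0.62, the membrane peptidase gene Mme −4.33 ± 1.13 and the probasin gene Pbsn −3.78 ± 1.13. None passed over all genes, and 3 passed adjusted over the list alone, all lower. This list was called by camera (adjusted p = 0.0018) but not with an estimated correlation (adjusted p = 0.405). Pten null array 2 stood below arrays 1 and 3 of its group on this list, with a mean of 7.69 against 10.15 and 10.09. It lay within the range of the PtenL/W;K-ras arrays (6.98 to 7.85), so the difference rested on Pten null arrays 1 and 3. Without Pten null array 2 the median was −2.21 (camera, adjusted p = 1.05e-06). The median was −1.09 without Pten null array 3 (adjusted p = 0.00893), −1.12 with the mean of probe sets (0.00505) and −1.02 after the filter (0.0158).

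Seminal vesicle genes separated 1 array from the other 5. Svs4, a seminal vesicle secretory protein gene, read 14.32 on Pten null array 2 and between 3.29 and 3.92 on the others, and the mean over the 7 measured genes was 12.18 on that array against 4.34 to 5.56 elsewhere. Svs6 and Svs3a read 8.69 and 7.20 on it, against at most 3.31 and 5.37 on the others, and Ceacam10 read 11.14 against at most 8.75. The list was not called between genotypes (adjusted p = 0.105), and was called as lower in PtenL/W;K-ras tumours without Pten null array 1 (adjusted p = 0.0201) or array 3 (0.0235). Without Pten null array 2 its median was 0.10 (adjusted p = 0.565), without array 2 of both groups 0.031 (0.931), and with array weights −0.21 (0.696). Smooth muscle genes followed the same array: Myh11, smooth muscle myosin, read 12.73 on it and at most 8.21 on the others, and Cnn1 12.43 against at most 7.24. Synpo2 and Synm read 10.53 and 10.94 on that array. Camera called the smooth muscle list as lower in PtenL/W;K-ras tumours (median −0.91, adjusted p = 0.0401), not with an estimated correlation (adjusted p = 0.66), and without Pten null array 2 the median turned to 0.056 (adjusted p = 0.87) and without array 2 of both groups to 0.22 (0.389). The smooth muscle list was not called without PtenL/W;K-ras array 1 (adjusted p = 0.0961) or array 2 (0.18) either. It also lost its call with the replicate block, after the filter (0.185) and with array weights (median −0.14, 0.696). The median was −1.45 without Pten null array 1 (0.00303) and −1.63 without array 3 (0.00125). Skeletal muscle genes stood out on PtenL/W;K-ras array 3, where the myosin gene Myh1 read 10.57 against at most 3.66 on the others, Tnni2 11.17 against at most 8.60, Atp2a1 9.98 and Pvalb 9.0. Camera called that list as higher (median 1.07, adjusted p = 0.036), not with an estimated correlation (adjusted p = 0.66), and without PtenL/W;K-ras array 3 the median was −0.085 (adjusted p = 0.868). It was not called without Pten null array 1 (adjusted p = 0.0526) or array 2 (0.0515) either, and the median rose to 1.82 without PtenL/W;K-ras array 1 (0.00208), 1.76 without array 2 (0.00276), 1.61 with array weights (0.0138) and 2.43 without array 2 of both groups (0.00912).

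**Figure D2:**
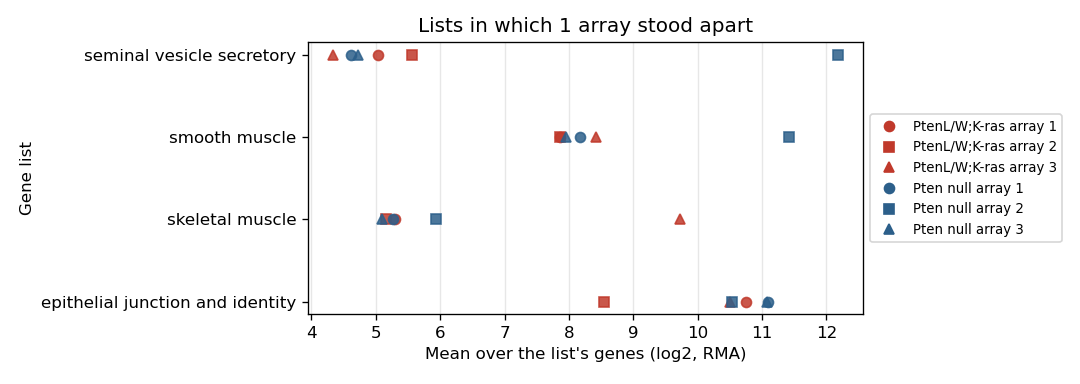
Mean over the genes of 4 lists (log2, RMA) on each of the 6 arrays, 1 marker per array. Pten null array 2 lies at 12.18 for seminal vesicle genes and 11.42 for smooth muscle genes, PtenL/W;K-ras array 3 at 9.73 for skeletal muscle genes and PtenL/W;K-ras array 2 at 8.54 for epithelial junction genes, each apart from the other 5 arrays.

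Fibroblast and collagen genes had a median difference of 1.39 (log2), with 16 of 21 members higher in PtenL/W;K-ras tumours and 9 of those without overlap. Col5a2 and Fap, fibroblast activation protein (1.97 ± 0.23, SE), were called over all genes. Fbln2, a matrix protein gene, read 2.26 ± 0.29 higher and the PDGF receptor gene Pdgfrb 2.50 ± 0.37. Adjusted over the list alone, 9 members passed, all higher. Camera called the list (adjusted p = 7.11e-06) but not with an estimated correlation (adjusted p = 0.38). On this list Pten null array 2 stood at a mean of 10.69, nearer the PtenL/W;K-ras arrays (10.72 to 11.26) than the other arrays of its group (9.60 and 9.78). Endothelial genes had a median of 0.84, with 14 of 14 members higher, and 9 passed adjusted over the list alone. The VE-cadherin gene Cdh5 read 1.81 ± 0.24 higher, the VEGF receptor gene Flt1 1.34 ± 0.24, Egfl7 0.88 ± 0.19 and the tight-junction gene Cldn5 1.17 ± 0.25. Camera called this list (adjusted p = 8.93e-08) but not with an estimated correlation (adjusted p = 0.38). Adipocyte genes were lower at 8 of 8 members, with a median of −1.08. Cidec read −1.56 ± 0.24, Fabp4 −1.21 ± 0.27, Retn −0.95 ± 0.22 and Adipoq −3.37 ± 1.03, and these 4 passed adjusted over the list alone. By camera the list was called (adjusted p = 2.3e-05) but not with an estimated correlation (adjusted p = 0.38). Of 7 nerve and glia genes, Nefl, neurofilament light chain, was called (2.40 ± 0.24) and S100b read 2.30 ± 0.43 higher, both passing adjusted over the list alone, while Sox10 and Gfap read −0.36 ± 0.33 and −0.12 ± 0.16. That list was not called (adjusted p = 0.206), with a median of −0.11 and a mean of 0.61.

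Macrophage and monocyte genes had a median difference of 1.44 (log2), with 15 of 16 members higher in PtenL/W;K-ras tumours. Only 4 of the 16 were without overlap, where 24.4% of all tested genes were. The lysozyme gene Lyz2 read 2.21 ± 0.51 higher (SE), the Fc receptor gene Fcgr3 2.16 ± 0.57, Itgam 2.10 ± 0.66 and the complement gene C1qc 1.55 ± 0.49, and no member passed over all genes or adjusted over the list alone. PtenL/W;K-ras arrays 1 and 3 lay at 2.07 and 1.96 above the Pten null mean (median over the list) and array 2 at 0.33. Array 2 thus lay below Pten null array 1 (0.40), and the groups overlapped. The list was called by camera (adjusted p = 1.14e-05) but not with an estimated correlation (adjusted p = 0.574). Neutrophil genes had a median of 1.02, and 6 of 12 passed adjusted over the list alone, all higher. Clec4d read 3.21 ± 0.68 higher, S100a8 2.19 ± 0.50, Trem1 1.17 ± 0.24 and Mmp8 0.96 ± 0.25. The list was called (adjusted p = 0.00127), not with an estimated correlation (adjusted p = 0.38) and not after the filter (0.0742). B and plasma cell genes were lower, with a median of −0.96, and 9 of 12 passed adjusted over the list alone, all lower. Jchain, the joining chain of secreted antibodies, read −4.08 ± 0.60, Pou2af1 −2.73 ± 0.47, Mzb1 −1.75 ± 0.31 and the IgA gene Igha −3.39 ± 0.84. Camera called this list (adjusted p = 2.9e-05) but not with an estimated correlation (adjusted p = 0.38). T cell genes were not called (median −0.36, adjusted p = 0.0938), but were called as lower without PtenL/W;K-ras array 3 (median −0.57, adjusted p = 0.00974), without Pten null array 3 (0.0454) or with array weights (0.0383). The median was nearer 0 without Pten null array 1 (−0.083, adjusted p = 0.409) and without PtenL/W;K-ras array 2 (−0.11, 0.296). Cd8b1 read −0.70 ± 0.28, Gzmb −0.89 ± 0.38, Gzma −0.77 ± 0.38 and Cd28 −0.36 ± 0.29.

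Interferon-response genes had a median difference of −1.29 (log2), with 11 of 12 members lower in PtenL/W;K-ras tumours and none without overlap. Mx1 read −1.89 ± 1.12 (SE), Ifit3 −2.10 ± 1.25, Rsad2 −1.80 ± 1.22 and Ifit2 −1.31 ± 0.91. The list mean was 8.19 on Pten null array 2 against 11.53 and 10.68 on arrays 1 and 3 of its group. This list was called by camera (adjusted p = 0.0431), not with an estimated correlation (adjusted p = 0.66). It was called in 2 of the 6 fits without 1 array (without PtenL/W;K-ras array 1, adjusted p = 0.00673, and without Pten null array 2, median −2.30, adjusted p = 2.49e-06). It was not called without PtenL/W;K-ras array 2 (median −0.81, adjusted p = 0.346) or array 3 (0.0767), without Pten null array 1 (median −0.52, 0.46) or array 3 (0.187), or after the filter (0.0807). Inflammatory cytokine and acute-phase genes were not called as a list (adjusted p = 0.148). Of 19 members, 4 passed adjusted over the list alone, all higher in PtenL/W;K-ras tumours: the chemokine genes Ccl7 (1.37 ± 0.20) and Ccl2 (1.92 ± 0.45), Csf2 (2.59 ± 0.63) and the interleukin gene Il6 (2.67 ± 0.67).

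Proliferation genes had a median difference of 0.91 (log2), with 23 of 23 members higher in PtenL/W;K-ras tumours, 16 without overlap, and none past the threshold over all genes or adjusted over the list alone. The replication licensing genes Mcm3 and Mcm6 read 1.18 ± 0.31 and 1.38 ± 0.61 higher (SE), Mki67 1.24 ± 0.39 and Birc5 1.5 ± 0.61. PtenL/W;K-ras array 2 lay 2.11 above the Pten null mean, and arrays 1 and 3 lay 0.25 and 0.39 above it. Camera called the list (adjusted p = 2.37e-06) but not with an estimated correlation (adjusted p = 0.66). Without PtenL/W;K-ras array 2 the median was 0.34 and camera still called it (adjusted p = 8.73e-06), as it did with array weights (0.46, 0.00129) and without array 2 of both groups (0.22, 0.000662).

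**Figure D3:**
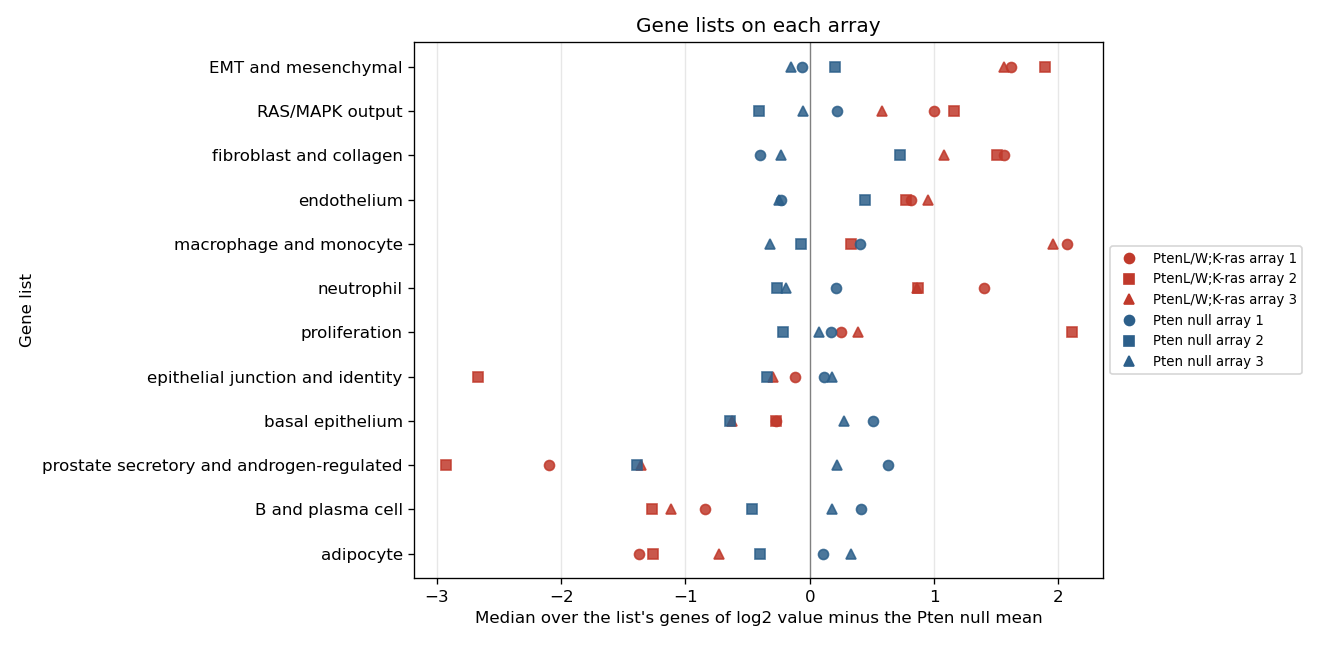
Median over each list's genes of the log2 value minus the Pten null mean, 1 marker per array, for 12 lists. For EMT and mesenchymal genes the PtenL/W;K-ras arrays lie between 1.56 and 1.89 and the Pten null arrays between −0.15 and 0.21. For epithelial junction genes PtenL/W;K-ras array 2 lies alone at −2.67.

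Mucin and goblet-cell genes had a median difference of 0.60 (log2). Gcnt3, a mucin glycosyltransferase gene, passed adjusted over the list alone and read 4.29 ± 0.85 higher (SE) in PtenL/W;K-ras tumours. Creb3l1 read 1.52 ± 0.40 and Tff2 1.39 ± 0.57 higher, and Spdef −1.39 ± 0.72. By camera the list was called (adjusted p = 0.0372), not with an estimated correlation (adjusted p = 0.66) and not without PtenL/W;K-ras array 1 (median 0.080, adjusted p = 0.279), PtenL/W;K-ras array 3 (0.36, 0.191) or Pten null array 2 (0.070, 0.237) or after the filter (0.187). The median was 1.88 without PtenL/W;K-ras array 2 (adjusted p = 8.73e-06), 1.37 without Pten null array 3 (0.00421) and 0.94 with array weights (0.00272). Of 7 urothelial genes, the keratin gene Krt20 passed adjusted over the list alone (4.25 ± 0.67 higher). Snx31, Upk1b and Upk1a read −0.31 ± 0.17, 0.87 ± 0.58 and −0.83 ± 0.76, and the list was not called (adjusted p = 0.79, median −0.20, mean 0.62). Neuroendocrine genes were called by camera as higher (median 0.67, adjusted p = 0.0235), not with an estimated correlation (adjusted p = 0.564) and not without PtenL/W;K-ras array 3 (median 0.084, adjusted p = 0.192). Without PtenL/W;K-ras array 2 the median was 1.10 (adjusted p = 0.00246) and without array 2 of both groups 1.06 (0.00474). Eno2 read 1.63 ± 0.52, Ncam1 1.66 ± 0.80, Uchl1 1.41 ± 0.79 and Scg2 1.04 ± 0.62 higher, with no member past the threshold adjusted over the list alone.

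Stem and progenitor genes were not called as a list (median 0.15, adjusted p = 0.104), except without Pten null array 3 (adjusted p = 0.0454), and the median was 0.26 without PtenL/W;K-ras array 2 (0.0885), 0.22 without Pten null array 2 (0.125), 0.24 without both (0.0788) and 0.29 with array weights (0.0808). Adjusted over the list alone, Procr (1.88 ± 0.32, SE) and Itga6 passed as higher and the aldehyde dehydrogenase gene Aldh1a1 (−3.25 ± 0.62) as lower in PtenL/W;K-ras tumours, and Aldh1a3 read 2.68 ± 0.90. Targets of FOXO transcription factors, which AKT signalling inhibits, went both ways (median −0.18, adjusted p = 0.722). Bcl2l11, a pro-apoptotic gene, read 1.03 ± 0.14 and Klf2 1.09 ± 0.22 higher, while Pik3ip1, an inhibitor of PI3K, read −1.37 ± 0.21 and Foxo3 −0.52 ± 0.13, and these 4 passed adjusted over the list alone. Hypoxia and glycolysis genes were called as higher (median 0.55, adjusted p = 0.036), not with an estimated correlation (adjusted p = 0.66) and not without PtenL/W;K-ras array 1 (0.148), array 2 (median 0.31, 0.0834) or Pten null array 2 (median 0.014, 0.734), after the filter (0.0807) or with array weights (median 0.30, 0.183). Without array 2 of both groups the median turned to −0.13 (adjusted p = 0.806), and without PtenL/W;K-ras array 3 it was 0.95 (0.00101). Ndrg1 passed adjusted over the list alone (1.25 ± 0.25), and P4ha1, Vegfa and Car9 read 1.64 ± 0.54, 0.81 ± 0.35 and 1.93 ± 0.90. Sterol and fatty acid synthesis genes were called as higher (median 0.31, adjusted p = 0.0492), not with an estimated correlation (adjusted p = 0.66) and not without PtenL/W;K-ras array 2 (median 0.17, 0.247), array 3 (0.202), Pten null array 2 (0.142) or array 2 of both groups (median 0.062, 0.327). It also lost its call with the mean of probe sets (median 0.19, adjusted p = 0.0668), after the filter (0.0807), with array weights (median 0.082, 0.325), with the replicate block and by camera on ranks (0.0521). Hmgcs1, an enzyme of cholesterol synthesis, was called over all genes (0.92 ± 0.12), and Sqle, Idi1 and Srebf1 read 0.75 ± 0.27, 0.89 ± 0.32 and −0.28 ± 0.13. The unfolded protein response list was not called (adjusted p = 0.995). Its 4 members with the largest moderated statistics were Herpud1 (−0.73 ± 0.17), Pdia4 (0.37 ± 0.21), Hsp90b1 (0.29 ± 0.17) and Edem1 (−0.25 ± 0.15). The list of genes induced by tissue handling was not called either (adjusted p = 0.827, median −0.25, mean 0.085), with Fos at 1.43 ± 0.37, Junb at 1.22 ± 0.32, Zfp36 at −0.38 ± 0.26 and Fosb at 0.43 ± 0.33. Its median lay between −0.17 and −0.043 in the fits without 1 array. In those fits the medians of other lists that were not called also moved: FOXO targets from −0.27 to −0.088, luminal genes from −0.68 to 0.24, squamous genes from 0.024 to 0.22 (0.79 after the filter), urothelial genes from −0.21 to −0.052, nerve and glia genes from −0.084 to 0.16, cytokine genes from −0.16 to 0.67 and unfolded protein response genes from −0.12 to 0.17.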

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

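The tests of tissue admixture, RNA quality, epithelial share and fibroblasts in this part were chosen after the results were seen, and the tests by other splits of the arrays and of a swapped label were set before their results. Probe sets without a gene name, or with several, were outside the gene-level comparison, and 23 of 10092 of them passed when every probe set was tested in limma, 16 higher and 7 lower in PtenL/W;K-ras tumours. The control probe sets for 18S ribosomal RNA, also outside the comparison, read 12.53 ± 0.23 on PtenL/W;K-ras arrays and 11.63 ± 0.32 on Pten null arrays (log2, mean ± SD, n = 3 each), a difference of 0.90 (0.896) with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allow.

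The real split called 102 genes and the highest of the other splits of the 6 arrays into 3 and 3 called 0, so 1 of 10 splits gave as many. At an unadjusted p under 0.05 the real split held 3037 genes. For gene lists by camera, the real split called 18 and the highest other split 20, so 2 of 10 splits gave as many. Each of the other splits, which mix the genotypes, called between 8 and 20 lists. They mix them unequally, so part of the genotype difference remains between the sides and the rest adds to the spread within them. Neither their list calls nor their 0 genes therefore show what is called without a genotype difference. With an estimated correlation camera called 0 lists in the real split. A camera call at the preset correlation is not taken by itself as evidence of a genotype difference. With 10 splits a share under 0.05 cannot be reached. The split with 20 set PtenL/W;K-ras array 1 and Pten null arrays 1 and 3 against the rest, and so placed array 2 of each group on one side.

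Pten null array 2 read high for seminal vesicle and smooth muscle genes. The 7 seminal vesicle genes, none of them on another list, read a median of 9.47 (log2) above the mean of Pten null arrays 1 and 3, all 7 above every other array, and Svs5 (named after its values were seen) read 15.02 on it and at most 7.26 on the others. Its 3' minus 5' differences for beta-actin and Gapdh lay −0.0767 and −0.197 from the mean of the other 5 arrays, which argues against degraded RNA. Tissue admixture would give such a median, but the median restates the pattern that raised the question and adds no support. Seminal vesicle tissue taken with the lobes is left as a candidate explanation. No biological explanation, such as a change within the tumour, was tested. A wrong genotype label stays open because values go both ways. At the 207 genes called without this array it lay nearer the Pten null mean at 53.6%. At the 200 genes with the smallest limma p in a fit without it, its median position was 0.435. There 0 is the mean of its own group and 1 that of the other. In like fits PtenL/W;K-ras arrays 2 and 3 lay at 0.442 and 0.336 and the other arrays between 0.00748 and 0.121. A middle position was therefore not particular to this array. Its list means for interferon genes (8.19) and prostate secretory genes (7.69) lay among the PtenL/W;K-ras arrays (7.90 to 9.86 and 6.98 to 7.85). Its first principal component (38.80, against 44.63 and 48.98 in its group and −72.55 to −21.25 in the other) ran with its label. So did its EMT list median (0.21, against 1.56 to 1.89) and its RAS/MAPK list median (−0.41, against 0.58 to 1.16). It correlated at 0.940 and 0.935 with its own group and at 0.910 to 0.928 with the other.

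PtenL/W;K-ras array 2 had low epithelial junction genes. Against the mean of arrays 1 and 3 of its group, the 23 members of the list other than Krt8, Krt18 and Krt19 had a median of −2.68 (log2), while those 3 keratins, named after their values were seen, had a median of −0.50. On the same comparison, fibroblast genes changed by 0.30 and macrophage genes by −1.68 on average, a difference of 1.97 (permutation p = 1e-05, the smallest that 100000 resamples can give, over genes, which are not independent). These were the highest and the lowest of the cell-type lists compared, chosen after their values were seen, so the p-value gives no support. The other lists changed by −0.498 (neutrophil) to 0.0574 (adipocyte) on average. Such unequal changes go against a smaller share of epithelial cells only if that share raises the other cell types alike. A smaller share in which the other types change unequally stays open. The 3' minus 5' differences of its control probe sets lay −0.237 and −0.114 from the mean of the other arrays, which argues against degraded RNA. A change within the tumour cells of this animal may remain as well, and no biological explanation was tested, since the design has no group for 1 array.

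The higher EMT and mesenchymal genes set the 2 genotypes apart. Without Pten null array 2 the list's median was 1.75 (log2). That array had the highest list mean of its group (8.55, against 8.19 and 8.11), so leaving it out could hardly lower the difference. These levels, rather than the fit without it, argue against that array as the source. Fibroblast and adipocyte genes differed by 3.15 in mean change without that array (exact permutation over genes, which are not independent, p = 1.7e-05). Both lists were chosen for this after their values were seen, so the p-value gives no support by itself. The difference goes against a lower epithelial share only if that share raises every other cell type alike. A lower epithelial share in which the other types change unequally stays open. More fibroblasts of the kind present in Pten null tissue stay open: the 21 members of the fibroblast list changed by a median of 1.39, with 16 higher and 5 lower, against 1.77 for the EMT list, so more fibroblasts, a changed kind of fibroblast and mesenchymal expression in tumour cells of this genotype cannot be told apart in whole-tumour RNA.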

How the results depend on the processing

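Of the alternatives, the 1 that leaves out both arrays that stand apart was chosen after seeing the data, and the cause of a change was not tested unless named. Against 102 called genes (95 of at least 2-fold), limma called 213 (178) after the filter at the median level, which tests fewer genes, 1561 (909) with array weights, 1034 (823) without array 2 of both groups, 176 (165) over all probe sets, 1 (1) by the ordinary test, which does not moderate variances across genes (2633 at an unadjusted p under 0.05), and 13 by treat, which asks for a larger change. With single arrays left out, which leaves fewer arrays, the number ranged from 1 to 303 (1 to 288). The mean of probe sets, both scalings and trend with robust gave 79 to 129, all within 1.5 times, and the scalings moved the median of all genes by less than 0.01. Array weights kept all 102 genes and leaving out both arrays kept 98.

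With the replicate block 0 genes were called by limma (0 of at least 2-fold), with 3146 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0623, and 16 lists, without the smooth muscle (adjusted p = 0.0548) and sterol (0.0578) lists. The values do not settle whether equal numbers pair the arrays. Same-numbered arrays' deviations from their group means correlated at 0.192, 0.20 and 0.073 over genes, and those of other pairs at −0.197 to 0.147. Of 6 arrays, 5 correlated best with the array of their own number.

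Against 18 called lists, camera called 8 after the filter (fewer genes tested), 0 with an estimated correlation (2 at an unadjusted p under 0.05) and fry 1, while other settings gave 13 to 20. Of the 18, 10 were called in all 6 fits without 1 array. The median of the smooth muscle list ranged from −1.63 to 0.056 with single arrays left out, turning without Pten null replicate 2, and was 0.22 without both arrays. That of the skeletal muscle list ranged from −0.085, without PtenL/W;K-ras replicate 3, to 1.82. Of the 30 genes named for size, 30 kept their call with array weights, with either scaling, with trend and robust and without both arrays, 27 with the mean of probe sets and 0 with the block. The filter kept 15 genes in the test, and all 15 kept their call. Without PtenL/W;K-ras arrays 1, 2 and 3 the numbers were 1, 29 and 17, and without Pten null arrays 1, 2 and 3 they were 3, 26 and 1. The medians of the luminal, squamous, nerve, cytokine and unfolded protein lists, none of them called, turned sign under at least 2 settings each. Values near 3 on the log2 scale lie at the floor of the arrays, so differences from them are compressed.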

Other observations

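The gene families in this part were chosen after the values were seen, and their camera tests were adjusted over the 9 families of at least 5 genes. Groups did not overlap at 24.4% of all tested genes, where chance gives 10%, and the counts without overlap below are to be read against this share. Matrix metalloproteinase genes had a median difference of 0.85 (log2, PtenL/W;K-ras minus Pten null) over 18 genes, 8 without overlap as higher and 0 as lower (camera, adjusted p = 2.09e-05). Beside Mmp13 and Mmp10, which were called, the macrophage elastase gene Mmp12 read 4.95 ± 1.16 (SE) and was not called (limma, adjusted p = 0.121). It read 8.54 on PtenL/W;K-ras array 2 against 12.78 and 12.31 on arrays 1 and 3. Adamts and Adamtsl genes had a median of 0.76 over 20 genes, 9 without overlap as higher, and collagen genes a median of 0.63 over 42, of which 15 lay without overlap as higher and 3 as lower (adjusted p = 2.09e-05 for both families). With an estimated correlation no family was called, with adjusted p of 0.194 for Mmp, 0.123 for Adamts and 0.345 for collagen genes. In the fits without 1 array, added after seeing the data, each of these 3 families stayed called, with a Mmp median of 0.54 without PtenL/W;K-ras array 2 (adjusted p = 8.35e-06) and a collagen median of 0.95 without Pten null array 2 (5.37e-08).

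Glutathione transferase genes had a median of −1.06 (log2) over 18 genes, 1 of them called, 7 without overlap as lower and 0 as higher (adjusted p = 7.93e-05, and 0.229 with an estimated correlation). Pten null array 2 held part of this: without it the median was −0.53 (adjusted p = 0.00124), and without array 2 of both groups −0.46 (0.0239), and Gstm1 read 12.82 on it against 9.29 and 9.56 in its group. Genes for acyl-CoA thioesterases and peroxisome biogenesis had a median of −0.22 over 26, with Acot6 (−1.44 ± 0.12, SE) and Pex11a (−1.36 ± 0.16) among the called genes (adjusted p = 0.000405, and 0.123 with an estimated correlation). Immunoglobulin genes had a median of −1.39 over 18 genes, 12 without overlap as lower and 0 as higher (adjusted p = 5.83e-08, and 0.188 with an estimated correlation), and a median of −0.81 without Pten null array 1 (1.18e-08). Aldehyde dehydrogenase, Wfdc and Serpin genes were not called as families (adjusted p = 0.192, 0.167 and 0.853), though Aldh genes were without PtenL/W;K-ras array 3 (median 0.072, camera direction lower, 0.0467) and Wfdc genes without Pten null array 2 (median −0.51, 0.0403), and Aldh6a1 was called as a gene (−2.29 ± 0.23).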
